A study of Danio rerio with 9 samples.

How the data were processed

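Liver RNA of 9 zebrafish libraries was measured by RNA sequencing, in 3 groups of 3. Per the labels' protocols, livers were snap frozen, total RNA was extracted with Qiagen kits, and 1 µg of RNA with an integrity number above 6.5 went into each library. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and the build danRer11, with no role or order. The annotation, strand setting and differential test are not given in the sources used here.

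The authors deposited 1 table of FPKM per gene and library, with 33716 gene IDs, and a table for each null against wild type. In those tables, per the file headers, the authors gave a mean read count per group, which is a signal value scaled by them in each table separately, a log2 ratio, a p-value and an adjusted p-value. Some cells of the deposited log2 column hold a spreadsheet error, so the log2 ratio was recomputed from the deposited group means. Of the gene IDs, 29201 had a symbol in the name table given with the data, and symbols in human capitals were printed in lower case. Genes without a symbol kept their ID. Gene order came from the RefSeq annotation of GRCz12tu, another build than the authors', so no coordinate was taken from it.

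Tables were read with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9. FPKM values are whole multiples of the value of 1 read, which allowed the reads per gene and library to be recovered. All 164584 values looked at below 1000 reads (100%) were whole within 0.05. Library totals ran from 46.1 to 54.5 M reads. At that depth, groups without a read were compared with a floor of 3 reads over the group, and floors cover counting error only. No pair of libraries within a group agreed within sampling noise.

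FPKM columns were rescaled by the median ratio to the geometric mean over 7660 genes with at least 1 FPKM in all 9 libraries. Genes with a mean of at least 0.5 FPKM were tested, 13290 in all. Values were log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust) fitted the 3 group means to all 9 libraries with 6 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale and understate the change of low genes. The design before the data were examined foresaw count tests if the deposited files held counts, which they did not.

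In all, 49 gene lists were fixed before the data were examined, and 47 had at least 5 genes tested. Of 1853 list symbols, 1495 matched. Lists were tested with limma camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. The genes named were chosen by a rule also fixed in advance. It took the targeted genes, then the 10 largest increases and 10 largest decreases called without overlap (5 and 5 for focad null against pdia6 null), leaving out placeholder names, and then up to 3 called members of each list that was called or had 3 called members. Where a list had no called member, 2 members with the lowest p are values only.

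The test was checked on counts simulated from the recovered reads, with 50 genes changed at each of 4 sizes in the focad null group (49 tested at 16-fold). For focad null against wild type, over 13178 genes, 10% of genes changed 2-fold, 44% of those changed 4-fold, 68% at 8-fold and 81.6% at 16-fold were recovered, and 6.48% of the calls were unchanged genes. Changes of 4-fold or less were therefore missed more often than they were found. A list raised 2-fold, nuclear oxidative phosphorylation, was called by camera with either correlation and by fry, with 0 of 46 other lists called. Genes were drawn independently in these simulations, whereas the estimated correlation within that list was 0.40 in the data. The check therefore does not show how camera or fry behave on lists with correlated members.

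Shared calls were compared with 100 simulated sets of unchanged groups. Alternatives were other pseudocounts, filters and scalings, fits of the 6 libraries compared, a replicate block, a plain fit, a fold threshold, each library left out in turn, and the authors' tables. After the data were seen, limma voom on the recovered reads, the omission of wild-type replicate 1 together with the library labelled pdia6 null replicate 1, intestine and pancreas scores as covariates, and matching of list members by human symbol were added.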

Results

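RNA from zebrafish liver was sequenced in 9 libraries, with 3 libraries from the wild-type AB line, 3 from maternal-zygotic focad null fish and 3 from maternal-zygotic pdia6 null fish. A maternal-zygotic null lacks the gene product from the egg as well as from its own genome. Focad encodes focadhesin, and pdia6 encodes a protein disulfide isomerase of the endoplasmic reticulum (ER). The wild-type and pdia6 null fish were 3.5 months old, and the labels used here give no age for the focad null fish. Each library held between 46.1 and 54.5 M reads assigned to genes. The labels do not say whether the libraries of a group came from separate fish, so the p-values measure the spread between these libraries, which may be technical. Reads of pairs within a group gave a chi-square per degree of freedom from 152 to 799.5, far beyond sampling noise. This argues against repeated sequencing of the same library, and other technical sources were not tested.

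The targeted transcripts were examined first. Focad (ENSDARG00000022020) stood at 1.13, 0.52 and 1.03 FPKM in wild-type replicates 1 to 3, at 0.28, 0.53 and 0.24 in the libraries labelled focad null, and at 1.21, 0.93 and 1.09 in the libraries labelled pdia6 null. The library labelled focad null replicate 2 (70 reads) thus lay inside the wild-type range, just above wild-type replicate 2 (67 reads). It goes against its label by this measure, although a null allele can leave its transcript in place. Genes that split focad null replicates 1 and 3 from wild type and pdia6 null mostly placed that library with its own group. They did so for 4 of 6, 15 of 18 and 52 of 83 genes, at gaps of 3, 2 and 1 log2 units. How often a wild-type library would lie there was not measured. On the log2(FPKM + 1) scale, that library held 0.11 of mhc1uba and 0.03 of urahb, against 8.26 to 9.85 and 4.92 to 5.07 in wild type. Hbe1 stood at 4.90 there, and at 0 to 0.19 in wild type. The library labelled focad null replicate 2 thus lay apart from wild type at these genes, which were picked with it among the focad null libraries. The log2 difference of focad between focad null and wild type was -0.48 ± 0.18 (SE), which did not pass the limma test (adjusted p = 0.276). An exact permutation test gave a 2-sided p of 0.2 against wild type, where 3 libraries against 3 cannot go below 0.1, and 0.0238 against the 6 other libraries. Pdia6 (ENSDARG00000009001) stood at 265, 14.2 and 56.4 FPKM in wild type and at 26.4, 26.0 and 17.8 in the libraries labelled focad null. It stood at 0.90 and 0.91 FPKM in pdia6 null replicates 2 and 3, but at 44.3 in the library labelled pdia6 null replicate 1, inside the wild-type range. The log2 difference from wild type was -3.49 ± 1.34 (SE; adjusted p = 0.336 with limma; exact p of 0.2 against wild type and 0.0952 against the 6 others). The library labelled pdia6 null replicate 1 therefore also goes against its label by this measure, although a null allele can leave its transcript in place. Both libraries were kept under their labels, and the group names below are those of the labels. That library also held 2359 FPKM of hspa5 and 2837 FPKM of hsp90b1, chaperones of the ER. The highest values of these genes in the other libraries were 734 and 810, both in wild-type replicate 1.

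**Figure D1:**
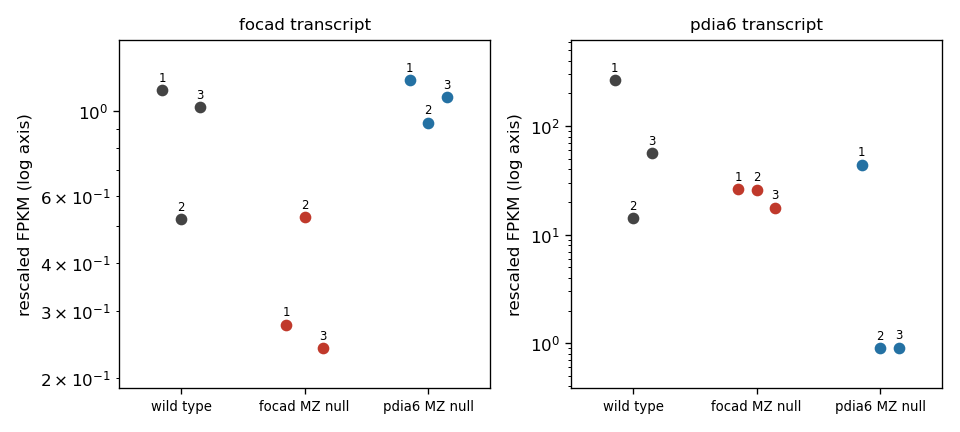
Rescaled FPKM (log axis) of the focad and pdia6 transcripts in each library, with groups on the horizontal axis and the replicate number above each point. Pdia6 lay at 0.90 and 0.91 FPKM in pdia6 null replicates 2 and 3 and at 44.3 in the library labelled pdia6 null replicate 1.

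The first comparison asked which liver transcripts differed between the libraries labelled focad null and wild type. Transcripts of the major histocompatibility complex class I genes mhc1uba and mhc1uca, which encode antigen-presenting proteins, were close to absent in the libraries labelled focad null. Mhc1uba had 10 reads there and mhc1uca 1, and the libraries labelled pdia6 null were as low, with 9 and 0 reads. The sample titles name AB for wild type only, so a difference in line cannot be told apart from the genotype. Mhc1uba fell by 8.81 on the log2 scale (SE 0.36, adjusted p = 1.155e-05), from 535 ± 335 FPKM (SD, n = 3) to 0.056 ± 0.036. Urahb, an enzyme of uric acid breakdown, fell by 4.99 (SE 0.14, adjusted p = 8.439e-07), from 31.0 ± 1.7 FPKM to a single read in the 3 libraries labelled focad null. Ddit4, a stress-induced inhibitor of TOR signalling, rose by 3.35 (SE 0.62, adjusted p = 0.0418), from 6.24 ± 4.09 to 63.8 ± 20.3 FPKM. Nupr1b, a stress-induced transcriptional regulator, rose by 2.33 (SE 0.34, adjusted p = 0.0121), from 102 ± 34.5 to 501 ± 39.62 FPKM.

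Among the largest increases, hbe1 (ENSDARG00000097238), a globin, went from 0.046 ± 0.080 to 28.6 ± 1.8 FPKM, a log2 change of 4.82. Its symbol is shared by 7 gene IDs, so reads may be split between copies. The complement protease gene c1s.2 rose by 5.15 and the complement regulator gene cfhl2 by 5.32. Nlrp3l2 had no read in wild type and was at least 1222-fold higher in the libraries labelled focad null, taking 3 reads over the group as the floor. Rab3c, fos, htatip2 and oclna rose by between 2.78 and 2.90 on the log2 scale. One of the 1947 gene IDs with the symbol 5s_rrna (ENSDARG00000112529) also rose, and reads of such a repeated gene cannot be assigned with certainty. Among the largest decreases, haptoglobin (hp) went from 884 ± 530 to 9.69 ± 6.74 FPKM and cbln11 from 317 ± 208 to 6.45 ± 6.80. The log2 change was -4.44 for igflr1, -4.06 for znf1179, -3.85 for lnc.85, -3.52 for mhc1uca, -3.48 for cyp46a1.2 and -3.47 for rnasek. Lnc.85 had no read in any of the 6 libraries labelled null.

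Groups of genes fixed in advance gave few calls of single members. In the integrated stress response list, 2 of 32 genes tested rose, ddit4 and nupr1b, and 3 did when adjusted over the list alone. In the oxidative stress list 1 of 30 rose, the ferritin gene fthl27 (log2 change 2.35), and 2 adjusted over the list alone. Among 20 acute phase genes 1 fell, hp, and 3 adjusted over the list alone. One of 30 complement genes fell, c3a.3, by 1.41, and 1 of 22 coagulation genes, pros1, by 3.34, with the same counts adjusted over the list alone. In the hepatocyte marker list 1 of 29 fell, again hp, and 3 adjusted over the list alone. None of 37 genes of fatty acid oxidation and none of 28 of fatty acid synthesis passed the test, against 3 and 4 higher adjusted over the list alone. Ehhadh, a peroxisomal enzyme, stood at 77.9 ± 18.6 FPKM against 34.8 ± 4.6, and thrsp, a regulator of lipid synthesis, at 2097 ± 1072 against 280 ± 363. No gene of the ER chaperone list (51 tested, median log2 -0.40), the ribosome biogenesis list (50 tested, median -0.22), the amino acid metabolism list (44 tested, median -0.41) or the nuclear oxidative phosphorylation list (63 tested, median 0.42) passed. The 29 genes of the SKI complex and cytoplasmic mRNA decay had a median log2 change of -0.08, and the list was not called (camera adjusted p = 0.534).

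Markers of other organs were examined next. The 20 intestine markers had a median log2 change of 3.00, and 12 were higher adjusted over the list alone, although none passed over all genes tested and the list had an adjusted p of 0.539 with an estimated correlation. Fabp2, an intestinal fatty acid binding protein, stood at 237, 3640 and 71.1 FPKM in the libraries labelled focad null replicates 1 to 3 and at 2.597, 6.05 and 4.72 in wild type (adjusted p = 0.0504). Of 18 exocrine pancreas markers 1 rose, spink4 (log2 change 2.41), and 6 adjusted over the list alone (adjusted p = 0.539 with an estimated correlation). The centred exocrine median was 0.35 in the library labelled focad null replicate 2, below wild-type replicate 2 (0.43). The 5 endocrine pancreas markers were higher adjusted over the list alone and none passed over all genes tested (adjusted p = 0.539 with an estimated correlation), and insulin (ins) stood at 118 ± 99.2 FPKM against 1.53 ± 1.25 (adjusted p = 0.0844). The median of the intestine list, centred on its mean over the libraries, was 2.21, 4.22 and -0.30 in the libraries labelled focad null replicates 1 to 3 and -1.06, -0.99 and -0.74 in wild type. The gene groups above were measured in these same libraries.

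**Figure D2:**
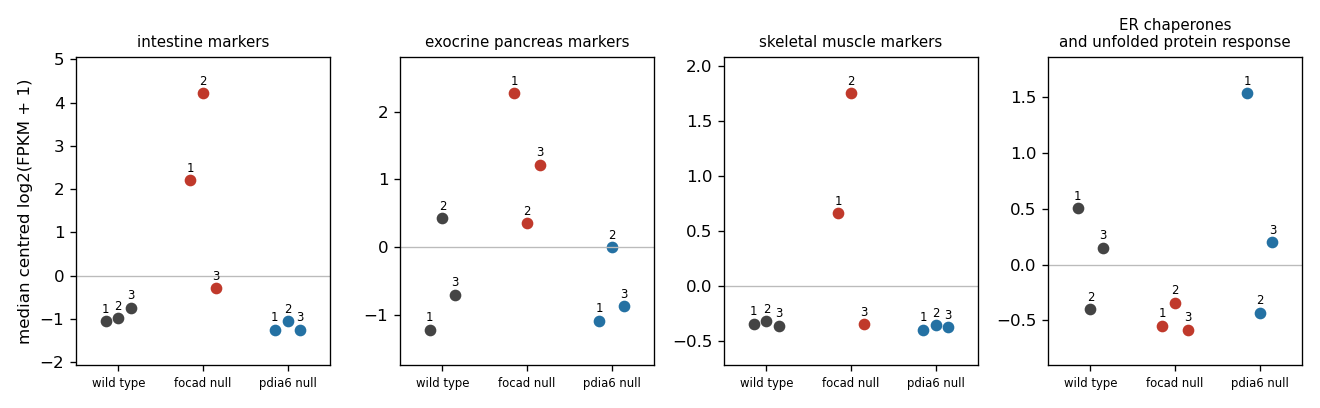
Median over the genes of 4 lists of log2(FPKM + 1), each gene centred on its mean over the 9 libraries, by group on the horizontal axis with the replicate number above each point. Intestine markers were highest in the library labelled focad null replicate 2 (4.22) and replicate 1 (2.21), and the ER chaperone list was highest in the library labelled pdia6 null replicate 1 (1.54).

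Over all 13290 genes tested, 207 differed between focad null and wild type at the adjusted threshold, 83 higher and 124 lower, and all 207 had libraries that did not overlap between the groups. Such separation held for 20.04% of all genes tested, where chance gives 10%. The camera test called 17 of 47 lists, and none held with an estimated correlation (adjusted p from 0.539 to 0.836 over the 17 lists). Mixed groupings of the same 6 libraries called up to 14 lists and 0 genes. Each such grouping keeps part of the genotype difference, so it does not measure the spread between libraries alone. The list calls were therefore not set apart from that spread. Calls ended without focad null replicate 3 for fatty acid synthesis, fatty acid oxidation and the integrated stress response (medians 0.40, 0.29 and 0.20), without the library labelled focad null replicate 2 for mitochondrially encoded transcripts, amino acid metabolism and ribosome biogenesis (0.15, -0.09 and -0.05), without wild-type replicate 1 for ER chaperones and ribosome biogenesis (-0.22 and -0.07) and without wild-type replicate 2 for amino acid metabolism (-0.12). Calls held but medians shrank for nuclear oxidative phosphorylation without the library labelled focad null replicate 2 (0.25), for exocrine pancreas without focad null replicate 1 (0.89) and for amino acid metabolism and fatty acid synthesis without wild-type replicate 3 (-0.26 and 0.26). The count of genes was 484 without focad null replicate 3, 89 without focad null replicate 1, 123 without wild-type replicate 2 and 124 without wild-type replicate 3, and 96 with limma voom on recovered reads. It was 136 without wild-type replicate 1 and the library labelled pdia6 null replicate 1, and 12 with intestine and pancreas scores as covariates. Mhc1uba, mhc1uca, urahb, hbe1, rnasek, igflr1, htatip2, oclna, rab3c, nlrp3l2, lnc.85 and cyp46a1.2 passed without each of the 9 libraries in turn, whereas ddit4 passed in 3 of the 9 fits, hp in 2, fos in 1, fthl27 in 1, spink4 in 1, pros1 in 3, c3a.3 in 3, znf1179 in 4, nupr1b in 6, cfhl2 in 6, c1s.2 in 7, cbln11 in 7 and the 5s_rrna gene in 8. Of the genes that passed in all 9 fits, nlrp3l2 and lnc.85 did not pass with limma voom (adjusted p = 0.0589 and 0.0922). With the covariates, only mhc1uba, urahb, hbe1 and rnasek of the genes that passed in all 9 fits still passed, as did the 5s_rrna gene (limma adjusted p = 0.0441). The covariates overlap the genotype, so a call lost in that fit cannot be assigned to intestine or pancreas tissue.

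In the authors' deposited table for focad null against wild type, 295 genes were called, 125 higher and 170 lower. Of these, 209 were among the genes tested here, all 209 with the same sign, and 127 were also among the 207.

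The second comparison asked which transcripts differed between the libraries labelled pdia6 null and wild type. Mhc1uba fell by 8.82 on the log2 scale (SE 0.36, adjusted p = 7.643e-06), to 0.051 ± 0.047 FPKM (SD, n = 3). Cbln5 fell by 6.40 (SE 0.39, adjusted p = 0.000133), from 88.1 ± 28.9 to 0.010 ± 0.017 FPKM. Sat2a.2, named for a polyamine acetyltransferase, had no read in wild type and 86.1 ± 22.5 FPKM in the libraries labelled pdia6 null, at least 3571-fold higher with 3 reads over the group as the floor. Ehhadh rose by 1.73 (SE 0.26, adjusted p = 0.0206), from 34.8 ± 4.6 to 118 ± 21.2 FPKM. Slc25a20, the mitochondrial carnitine carrier, rose by 1.13 (SE 0.21, adjusted p = 0.0443), from 79.7 ± 5.7 to 176 ± 17.1 FPKM.

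Among the other increases, c1s.2 rose by 5.14, itln1 by 3.55, phf20l1 by 3.54, steap4 by 3.04, fam20b by 2.82, oclna by 2.74, tmem123 by 2.63 and ftcdnl1 by 2.45. The symbol itln1 is shared by 2 gene IDs. A 5s_rrna gene (ENSDARG00000108005) rose by 3.32, with the same uncertainty as above. Among the decreases, suox, a sulfite oxidase, went from 50.4 ± 10.8 to 2.71 ± 0.47 FPKM. Caspa, a caspase, went from 12.8 ± 4.9 to 0.11 ± 0.083 FPKM. The log2 change was -4.99 for urahb, -3.85 for lnc.85, -3.82 for ptgr1.1, -3.52 for mhc1uca, -3.41 for rnasek and -3.12 for pcnp. The symbols rnasek and pcnp are each shared by 2 gene IDs.

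In the fatty acid oxidation list 2 of 37 genes rose, ehhadh and slc25a20, and 8 adjusted over the list alone. In the interferon list 1 of 35 fell, mhc1uba, with the same count adjusted over the list alone. The autophagy and lysosome list had a median of -0.31. None of 51 ER chaperone genes passed. Derl3, a component of ER-associated degradation, stood at 81.3 ± 90.1 FPKM against 13.9 ± 11.3, a spread set by the library labelled pdia6 null replicate 1. The median of the ER chaperone list was 0.36 with that library and -0.17 without it. None of 30 complement, 22 cholesterol synthesis and 44 amino acid metabolism genes passed, with list medians of -0.31, -0.86 and -0.55, and 1 complement gene was lower adjusted over the list alone. The cholesterol median was -0.19 without wild-type replicate 1 (camera adjusted p = 0.413) and -0.57 without pdia6 null replicate 3. Wild-type replicate 1 held 8.05 FPKM of fdft1 against 1.73 in each of the other wild-type libraries. Prodha, an enzyme of proline breakdown, stood at 5.01 ± 1.47 FPKM against 40.7 ± 11.8 (adjusted p = 0.0876).

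In all, 163 of 13290 genes were called, 69 higher and 94 lower, all without overlap between the groups, a separation found for 20.6% of all genes tested. Camera called 7 of 47 lists, and none held with an estimated correlation (adjusted p from 0.860 to 0.905 over the 7 lists). Mixed groupings of the same 6 libraries called up to 18 lists and 3 genes. With the same limit, the list calls were again not set apart from the spread between libraries. Calls also ended without wild-type replicate 2 for ER chaperones, the interferon response, amino acid metabolism and complement (medians -0.03, -0.14, -0.35 and -0.22), without wild-type replicate 1 for complement (-0.30), without wild-type replicate 3 for autophagy and lysosome and ER chaperones (-0.26 and 0.34), without the library labelled pdia6 null replicate 1 for amino acid metabolism (-0.34) and without pdia6 null replicate 2 for complement (-0.03), and without single libraries labelled focad null for ER chaperones (0.36 each) and complement (-0.31 and -0.29). The count of genes was 98, 80 and 108 without the libraries labelled pdia6 null replicates 1, 2 and 3, 74 and 90 without wild-type replicates 2 and 3, 99 and 256 without the libraries labelled focad null replicates 1 and 2, and 78 with limma voom on recovered reads. It was 107 without wild-type replicate 1 and the library labelled pdia6 null replicate 1. Slc25a20 passed in 1 of the 9 fits that leave out 1 library, fam20b in 2, steap4 in 3, ehhadh and phf20l1 in 5, tmem123 in 6 and c1s.2 in 7, and the other called genes named here in all 9. Of those others, caspa, lnc.85, pcnp and the 5s_rrna gene did not pass with limma voom (adjusted p = 0.0680, 0.0978, 0.0541 and 0.0574). In the authors' deposited table for this comparison, 428 genes had an adjusted p below the same threshold of 0.05, 198 higher and 230 lower. Of these, 298 were among the genes tested here, all 298 with the same sign, and 135 were also among the 163.

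The 2 groups labelled null shared part of their calls. Both held 53 genes called lower and 18 called higher, and 0 called in opposite directions. The counts were 28 and 6 without focad null replicate 1, 29 and 11 without pdia6 null replicate 2, 35 and 8 with a replicate block, 23 and 10 with limma voom, and 6 and 2 with intestine and pancreas scores as covariates. Among them were mhc1uba, mhc1uca, urahb, lnc.85 and rnasek on the lower side and c1s.2 and oclna on the higher side. In 100 sets, all 9 libraries were simulated with no gene changed, and both null groups were set against the same simulated controls. These sets gave 0 shared calls in each direction, and independent lists would share 0.88 and 0.43. Sets without changed genes hold few calls to share, so their 0 cannot weigh on shared controls. The covariance of the log2 changes across genes was 0.167, against 0.097 in the simulations, a difference of 0.070. Their correlation across genes was 0.35, against 0.50 in the simulations. The simulated covariance already includes shared controls, but with genes drawn independently of each other. With 3 wild-type libraries no split leaves 2 on each side, so shared controls whose genes vary together may still give part of the excess.

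The third comparison set the libraries labelled focad null directly against those labelled pdia6 null, which tests the difference between their effects. In focad null relative to pdia6 null, sat2a.2 was lower by 6.39 (SE 0.20, adjusted p = 1.472e-06) and igflr1 by 5.22. Cbln5 was higher by 5.72 and hbe1 by 4.81 (SE 0.15, adjusted p = 1.472e-06). On the log2(FPKM + 1) scale, sat2a.2 stood at 0 in every wild-type library. Cbln5 stood at 5.80 to 6.76 in wild type and 4.88 to 6.18 in focad null, so both differences lay mainly on the pdia6 null side. Itln1 was lower by 3.49 and cbln11 by 5.59. Ccl39a.10, a chemokine, had no read in the libraries labelled focad null and 167 ± 58.8 FPKM (SD, n = 3) in the libraries labelled pdia6 null, while wild type stood at 25.9 ± 27.3. Mia had no read in the libraries labelled pdia6 null and stood at 41.3 ± 18.98 FPKM in the libraries labelled focad null. Fabp2 and the chitin synthase gene chs1 were higher in the libraries labelled focad null, by 7.24 and 5.64, beside the intestine markers. In the p53 target list none of 17 genes passed over all genes tested and 5 were higher adjusted over the list alone. None of 8 adipocyte markers passed, against 5 higher adjusted over the list alone.

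In this comparison 160 genes were called, all without overlap, a separation found for 24.4% of genes tested, with 81 higher and 79 lower in focad null (50.6% higher, against 55.4% with FPKM as deposited and 41.5% with quantile normalization). Camera called 16 lists, none with an estimated correlation (adjusted p from 0.277 to 0.742 over the 16 lists), and mixed groupings of the same 6 libraries called up to 17 lists and 1 gene. The count of genes was 60 and 631 without focad null replicates 1 and 3, 77, 90 and 98 without the libraries labelled pdia6 null replicates 1, 2 and 3, and 73 with limma voom on recovered reads. It was 67 without wild-type replicate 1 and the library labelled pdia6 null replicate 1, and 3 with intestine and pancreas scores as covariates. Fabp2 and chs1 passed in 2 of the 9 fits that leave out 1 library, mia in 3, ccl39a.10 in 4 and cbln11 in 7, and hbe1, sat2a.2, cbln5, igflr1 and itln1 in all 9. Cbln5 did not pass with limma voom (adjusted p = 0.0510).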

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

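The tests of pdia6 reads and of intestine markers were chosen after those results were seen, and those of linked variants and of other splits before.

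What flagged each gene and list in this paragraph is a difference between the effects of the 2 nulls, tested directly as focad null minus pdia6 null. For genes in the focad null calls the log2 difference was 4.81 for hbe1, 4.64 for ddit4, 3.15 for htatip2, 3.24 for nupr1b, -5.59 for cbln11, -5.22 for igflr1 and -3.44 for cyp46a1.2, and it was -2.44 for selenos and 7.24 for fabp2, neither of which was in those calls. For genes in the pdia6 null calls it was -6.39 for sat2a.2, -3.49 for itln1, -3.32 for the 5s_rrna gene, -2.85 for tmem123, -2.55 for ftcdnl1, 5.72 for cbln5, 3.01 for suox and -1.28 for slc25a20. For lists, the median log2 difference was -0.26 for ribosome biogenesis, -0.90 for ER chaperones, 0.70 for oxidative stress, 0.47 for p53 targets, -0.27 for acute phase proteins and 0.84 for the interferon response. It was 1.21 for cholesterol synthesis, 0.19 for nuclear oxidative phosphorylation, 0.38 for autophagy and lysosome, 1.73 for exocrine pancreas, 1.86 for endocrine pancreas and 2.97 for intestine markers. Calls ended for ribosome biogenesis without the library labelled focad null replicate 2 (-0.04) or pdia6 null replicate 2 (-0.05), and for nuclear oxidative phosphorylation without the library labelled focad null replicate 2 (0.04) or the library labelled pdia6 null replicate 1 (0.14). The call for acute phase proteins ended without any 1 of 5 libraries (medians from -0.35 to -0.20). The ER chaperone median was -0.47 without the library labelled pdia6 null replicate 1, the cholesterol synthesis median 0.71 without the library labelled focad null replicate 2 and the autophagy and lysosome median 0.23 without pdia6 null replicate 2. No list call held with an estimated correlation (adjusted p from 0.277 to 0.742).

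The library labelled pdia6 null replicate 1 held pdia6 reads inside the wild-type range. A wild-type library under this label was argued against by 8 of 9 genes (88.9%), mhc1uba and urahb among them. These genes split wild type from the other libraries labelled null by 3 log2 units. Wild-type libraries left out in turn lay away from their own group at 10% to 20% of such genes. For a focad null library, 4 of 5 such genes (80%) lay away, hbe1, igflr1 and the intestine marker fabp2 among them. That share cannot argue against this source. Focad null replicate 3, left out in turn, lay away from its own group at 93.4% of 61 genes. Both shares missed the bound of 90% set for these tests. Of genes that split pdia6 null replicates 2 and 3 from the 6 other libraries, 3 of 4 (75%) placed the library labelled pdia6 null replicate 1 with those replicates. Sat2a.2 and cbln5 were among them, and this share also missed the bound of 90%. Left out in turn at a gap of 3, pdia6 null replicates 2 and 3 lay with their own group at 100% of 4 and 50% of 8 genes. Gaps of 2 and 1, tried afterwards for the library labelled pdia6 null replicate 1, gave 70.6% of 17 and 67.9% of 81 genes. Judged the same way at a gap of 2, the libraries labelled focad null lay with those replicates at 4.76% to 17.4% of genes and the wild-type libraries at 13.04% to 21.7%, a control added after the other shares were seen, which argues against both sources. A transcript raised with other ER chaperone genes fitted its prediction. In the library labelled pdia6 null replicate 1, pdia6 had a residual of -3.41 log2 units from the line on hspa5, hsp90b1 and pdia4. The residuals were -0.58 to 0.56 in the 6 libraries labelled wild type and focad null. The line was extended past their highest mean (11.3 against 9.29). Pdia6 null replicates 2 and 3 also lay below the line, at -3.89 and -5.05. Their chaperone means of 4.57 and 6.49 lay inside the range of those 6 libraries. The residual therefore shows pdia6 low for its chaperone level, and cannot tell whether the transcript was raised with those genes. The genotype could not be read from these files.

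Among the libraries labelled focad null, 19 of 20 intestine markers (95%) were highest in replicate 2, then replicate 1, then replicate 3. This order says nothing of where replicate 3 lay relative to wild type. Tissue from outside the liver in the sample fitted its prediction, since skeletal muscle markers also lay 0.98 and 2.07 log2 units above the highest wild-type library in the libraries labelled focad null replicates 1 and 2. The focad genotype could not be told apart from it, with an exact permutation p of 0.1, the lowest that 3 libraries against 3 allow. These predictions were written after the order of the libraries had been seen.

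For the 53 genes called lower in both nulls, linked sequence variants between the lines were tested as adjacent pairs in the gene order. There were 2 pairs, against a median of 0 in 10000 random sets (permutation p = 0.0166). This met the prediction for linked variants among the genes with a position. It cannot tell for the 53 genes as a whole, since 25 of them (47.2%) had a position. Of the 53 genes, 7 had 3 reads or fewer in each null group. Shared wild-type libraries may account for part of the 53 genes. Simulated unchanged groups gave 0 shared calls but hold few calls to share, so they cannot weigh on this. A shared effect of both genotypes was not tested.

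Too few splits of 6 libraries exist to test the counts of calls. Of 10 splits, the real one called 207, 163 and 160 genes for focad null against wild type, pdia6 null against wild type and focad null against pdia6 null, and the highest other split 0, 3 and 1. For lists the real split called 17, 7 and 16, and the highest other 14, 18 and 17. As many lists as in the real split were called in 1, 9 and 3 of the 10 splits.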

How the results depend on the processing

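Of the alternatives, limma voom on recovered reads, the omission of 2 libraries together, the covariates and human symbols were chosen after the data were seen. Genes called in focad null against wild type (207) numbered 98 at a mean FPKM of at least 2, 121 with a replicate block, 96 with voom, 136 without wild-type replicate 1 and the library labelled pdia6 null replicate 1, 12 with covariates, and 89 to 484 without 1 library. For pdia6 null against wild type (163) they numbered 91, 82, 78 and 107 in the first 4 of these, 428 in the authors' deposited table and 74 to 256 without 1 library. For focad null against pdia6 null (160) they numbered 254 with a pseudocount of 0.1, 82 with the block, 73 with voom, 67 without the 2 libraries, 3 with covariates and 60 to 631 without 1 library. Genes higher in both nulls (18) numbered 28 and 11 with pseudocounts of 0.1 and 4, 11 at a mean FPKM of at least 2, 8 with the block, 10 with voom, 2 with covariates and 6 to 27 without 1 library. Genes lower in both (53) numbered 25 at a mean FPKM of at least 2, 34 with only the 6 libraries compared, 35 with the block, 23 with voom, 6 with covariates and 28 to 59 without 1 library.

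Lists called by camera fell from 17, 7 and 16 to 0, 0 and 0 with an estimated correlation and to 0, 0 and 2 with fry. They numbered 11 and 7 with covariates for focad null against wild type and against pdia6 null. For pdia6 null against wild type they numbered 11 with human symbols, 11 with only 6 libraries, 12 with the block, 12 with voom and 5 to 13 without 1 library.

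With covariates the sign turned, in focad null against wild type, for the lists of endocrine pancreas (-0.2329), ER chaperones (0.5784), intestine (-0.3122), mitochondrially encoded transcripts (-1.0773) and ribosome biogenesis (0.0579), and for gar1 (0.0621), ins (-0.1618), mt-nd1 (-0.4502), mt-nd4 (-0.6087), pdia2 (-0.313), pdia6 (1.4377) and sst1.2 (-0.2329). In focad null against pdia6 null it turned for acute phase proteins (0.1483), endocrine pancreas (-0.7675), ER chaperones (0.2668), interferon (-0.2808), intestine (-0.3511), nuclear oxidative phosphorylation (-0.0956) and ribosome biogenesis (-0.0303). The covariates are made from the markers themselves and overlap the genotype, so this fit is circular for the intestine and pancreas lists. For other lists and genes, the overlap leaves open whether a lost or turned change came from those tissues. Leave-one-out medians of the ER chaperone list in pdia6 null against wild type ran from -0.1651 (without the library labelled pdia6 null replicate 1) to 0.8785, and log2 changes of focad in pdia6 null from -0.0057 to 0.2403. The causes of the other changes were not tested.

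Replicate numbers are not known to pair samples, and libraries of the same number correlated between -0.19 and 0.29, so the block is only a check, and not every library correlated best with its own number. The count tests planned in case counts were deposited were not run, since none were, and limma voom on the recovered reads is the test on counts here. Depth limits genes near the floor of 3 reads per group. FPKM as deposited, quantile normalization and limma without trend and robust moved no count of calls past 1.5 times, and the share of calls that were higher in focad null against wild type was 40.1%, against 48.4% with FPKM as deposited and 35.8% with quantile normalization. For focad null against pdia6 null it was 50.6%, against 55.4% and 41.5%, so the side with more calls depended on the scaling, and for pdia6 null against wild type 42.3%, against 47.0% and 44.2%.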

Other observations

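The test of genes near the targeted genes was chosen before the results were seen. Cytosolic ribosomal protein genes in the libraries labelled pdia6 null had negative log2 changes for 64 of 67 genes, with a median of -0.22 (camera adjusted p = 0.0569, and 0.929 with an estimated correlation). The centred median of that list was -0.57 in the library labelled pdia6 null replicate 1 and 0.13 and 0.02 in replicates 2 and 3, against -0.21, 0.33 and 0.11 in wild-type replicates 1 to 3. Erythrocyte markers had a median of 0.49 there (11 genes, adjusted p = 0.0569), and adipocyte markers a median of 1.302 between focad null and pdia6 null (8 genes, adjusted p = 0.00263 with camera, 0.277 with an estimated correlation, 0.00338 with fry).

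The hypothesis that variants linked to the targeted alleles give calls near them was tested within 100 genes on either side. Near focad 3 genes were called in focad null against wild type (permutation p = 0.025 against random sets), and near pdia6 0 were called in pdia6 null against wild type. The focad count met the prediction for linked variants among genes with a position, and the pdia6 count did not. Random sets also had a median of 0 near pdia6, so a count of 0 there does not argue against linked variants. Neither count can tell for all called genes, since 59.4% and 55.8% of called genes had a position.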
